A study of Mus musculus with 6 samples.

How the data were processed

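Expression was measured on 6 Affymetrix arrays of mouse bone marrow stromal cells, 3 from mice of 3 months and 3 from mice of 18 months. Per the labels' protocols, femurs were crushed and digested with collagenase, cells were sorted on 4 surface markers and cultured, RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised. Groups and replicate numbers were taken from the sample titles. The values are the authors' deposited log2 expression values, one per probe set and array. The submitters' processing notes name MAS5, with no version, and how background, scaling and summarisation were done is otherwise not given in the sources used here. The values were used as deposited, with no further scaling. The deposited table carries no detection calls, so signal over background was judged from the control probe sets.

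The table held 72688 probe sets: 65956 transcript clusters, 5222 negative controls, 1324 positive controls, 155 ERCC spike-ins, 23 antigenomic background classes and 8 other controls. Kinds were read from the probe set names. The platform annotation listed 32750 probe sets. After symbols were updated through gene identifiers and synonyms of the RefSeq table of assembly GRCm38.p6, 31258 had 1 gene and 1492 had several, and 33206 transcript clusters had no listed gene and stayed unnamed. Of the probe sets with 1 gene, 31256 matched the RefSeq table. No coordinates are given, since the build of the array design is not given in the sources used here. Some genes of the fixed lists have no single-gene probe set here and were not analysed here.

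For each of 30701 genes the probe set with the highest mean over all arrays was kept; 442 genes had more than 1. Genes with a mean below the median of all transcript clusters (5.40 on the log2 scale) were left out of the tests, which kept 20190. Aged arrays were compared with young arrays by limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, and p-values were adjusted by Benjamini-Hochberg. Differences are aged minus young on the log2 scale, folds are 2 to the power of the difference, and errors are SDs of 3 arrays. An exact permutation test of a single gene cannot go below a two-sided p of 0.1 with these groups, so calls rest on the moderated model. Figures were drawn with matplotlib 3.10.9.

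Before the data were examined, 37 gene lists were fixed, of which 35 were tested with camera at a correlation of 0.01 and the sort markers and sex-linked genes were given by gene. A list needed at least 4 genes past the filter. Camera was repeated with an estimated correlation. Fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, passed 27 lists, and its mixed test passed 33. The rule for named genes was also fixed in advance. It takes, per direction, the 12 largest differences among genes past the test whose groups do not overlap, passing over predicted and clone names (3 among those higher and 1 among those lower), then up to 4 passing members with the smallest p from each list, and a set of stromal, senescence, sort and sex-linked genes.

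Alternatives were quantile normalization, median centring, no filter, leaving out the lower 70% of probe sets, the mean of all probe sets of a gene, eBayes without trend or with robust estimation, every probe set tested, an equal-variance test per gene, the replicate number as a block, each array left out in turn, and, added after the data were seen, a test against a difference of 0.3. All 10 splits of the arrays into groups of 3 were also fitted.

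The gene test was checked on simulated arrays with the means and spreads of the 20190 genes, of which 200 were changed. It recovered 14 of 50 genes changed by 0.25 on the log2 scale, 43 of 50 changed by 0.5, and 50 of 50 at differences of 1 and of 2, and it called 13 unchanged genes. The simulated noise was independent between genes, and far fewer genes were changed than the 40.6% called in the data. The recovery of small differences therefore does not carry over to the real comparison. The list test, on simulated lists of independent genes, recovered 10 of 10 lists moved by 0.3 and called 0 of 30 others; genes of the real lists are not independent.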

Results

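Bone marrow stromal cells (BMSCs), the plastic-adherent marrow cells that can form bone, fat and cartilage cells, were compared between mice of 3 and 18 months. The cells came from crushed, collagenase-digested femurs and were sorted as Sca-1 and CD29 positive and CD45 and CD11b negative. They were then grown in culture past the first passage before total RNA was taken. Gene expression was measured on 6 Affymetrix arrays, 3 from young and 3 from aged mice. The labels call the arrays of an age biological replicates without saying whether each came from its own animal, so the p-values measure the spread between these arrays. The comparison asks which genes of these sorted, cultured cells differ with the age of the donor.

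The array medians of the deposited log2 values lay between 5.39 and 5.44. Within an age the arrays were closely alike, with Pearson's r across genes from 0.995 to 0.999, and between ages r was 0.976 to 0.978 (genes are not independent replicates). The median gene had an SD of 0.07 between young arrays and 0.04 between aged arrays on the log2 scale. The number of arrays, 3 per age, limits the precision. The median negative control probe set had a mean log2 value of 4.79 and 95% of them lay below 7.61, so a value under 7.61 is within the range of the negative controls here. For genes with such a value in either age, levels or log2 differences between measured values are given and no fold, since the true ratio is not known. The antigenomic background classes, which match no mouse sequence, lay above 7.61 where rich in G and C. The class with 23 such bases read 8.87 in young and 9.11 in aged arrays. A value above 7.61 can thus still be background in a probe set rich in G and C.

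All 26 measured genes of the type I interferon response and 21 of 29 extracellular matrix genes rose with age, and 18 of 19 genes of the unfolded protein response fell. As lists these passed camera with a preset correlation, and with an estimated correlation they did not (adjusted p = 0.0885, 0.264 and 0.0734 with an estimated correlation). Of 20190 genes tested, 3724 rose and 4471 fell with age (limma, Benjamini-Hochberg adjusted p under 0.05). Which direction held more genes depended on the scaling, as median centring gave 3958 higher and 3842 lower. At least 2-fold changes ran mostly upward, with 411 genes higher and 42 lower, and 233 of the 411 had a young mean, and 22 of the 42 an aged mean, within the negative control range. Of all calls, 2031 had both means within it. The groups did not overlap in 10366 of the 20190 genes (51.3%), where chance gives 10% for groups of this size. The median called gene differed by 0.29 on the log2 scale, and 4089 of the calls (49.9%) were smaller than 0.29, the largest shift seen in the array's antigenomic background probes, which match no mouse sequence. When the difference was tested against 0.3 on the log2 scale, a setting chosen after that shift was seen, 1985 genes passed, 1169 higher and 816 lower. At the adjusted p threshold, with no minimum difference, 40.7% of the array's positive control probe sets passed, beside 40.6% of the genes. Whether young and aged samples shared a culture or hybridisation batch is not given in the sources used here, so batch and age cannot be told apart for these calls.

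**Figure D1:**
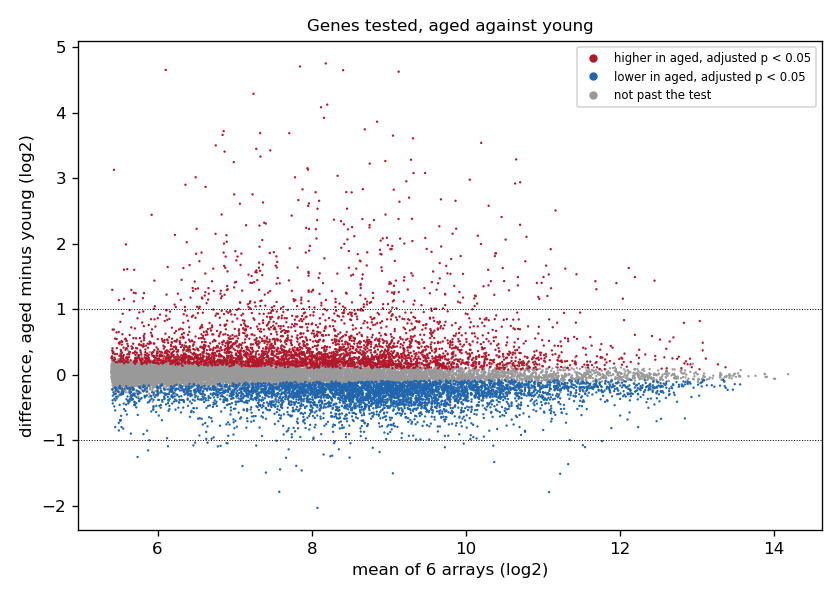
Each point is 1 of the 20190 genes tested, with its mean over the 6 arrays (log2) on the horizontal axis and its difference, aged minus young (log2), on the vertical axis; red and blue mark genes past the adjusted p threshold and dotted lines mark 2-fold. Of the genes beyond the dotted lines and past the test, 411 lie above and 42 below.

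The 12 named genes with the largest measured rises all had a young mean within the negative control range, so their order and exact size are not settled. Among them was Omd, which encodes osteomodulin, a small leucine-rich proteoglycan of mineralised matrix. It had a log2 value of 5.81 ± 0.35 (SD, n = 3) in young and 10.56 ± 0.02 (SD, n = 3) in aged cells (limma, adjusted p = 4.07e-08). Aspn, which encodes the related proteoglycan asporin, went from 3.78 ± 0.26 to 8.43 ± 0.18, a difference of 4.65. Il1rn, the interleukin 1 receptor antagonist, rose from 6.82 ± 0.21 to 11.44 ± 0.01. The interferon-inducible genes Oas2, Ifi206, Ifit3b, Phf11b and Iigp1 rose by 4.65, 4.70, 3.92, 3.74 and 3.66 on the log2 scale. Ctla2a, Ms4a4d, Hp (haptoglobin) and Aldh1a1 (a retinaldehyde dehydrogenase) rose by 4.12, 4.08, 3.86 and 3.69. Ifi206, Ifit3b, Phf11b and Ctla2a have near-identical family members, so their probe sets may read more than 1 gene and their values are uncertain in that respect.

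Measured decreases were smaller, and 7 of the 12 named ended within the negative control range, among them Dthd1, which went from 9.09 ± 0.02 to 7.06 ± 0.03 (SD, n = 3 each) and fell by 2.03 on the log2 scale (limma, adjusted p = 2.97e-09). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, fell by 1.79, from 11.98 ± 0.03 to 10.18 ± 0.02, or 3.46-fold. Sdf2l1 and Hyou1, which work with chaperones in the endoplasmic reticulum, fell by 1.51 and 1.36, and Ero1b, an oxidase of disulfide formation there, fell by 1.46. Dusp4, a phosphatase of MAP kinases, was 2.84-fold lower, and Slc40a1, the iron exporter ferroportin, fell by 1.39. Ostn, Chrnb1, Avil and Eid3 fell by 1.39, 1.44, 1.33 and 1.27. Prl2c2 fell by 1.49 and belongs to a family of near-identical genes, so its value is uncertain.

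**Figure D2:**
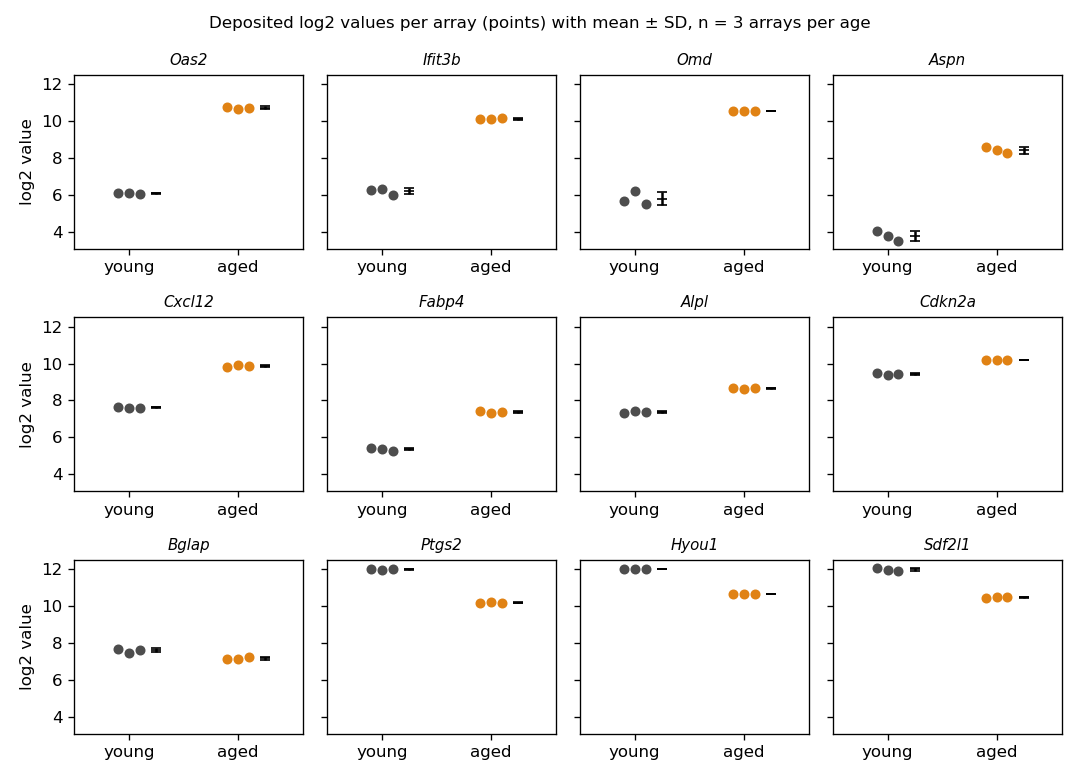
Deposited log2 values of 12 named genes on each of the 6 arrays (points), with the mean and SD of each age beside them. In each of the 12 genes the values of the 3 young and the 3 aged arrays do not overlap, which the naming rule required of those with the largest differences.

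Gene lists were fixed before the data were examined, and 35 were tested with camera at a preset correlation between genes. By that test 9 lists were shifted up and 2 down. No list passed when the correlation was estimated from these arrays, and 4 of the 10 splits of the arrays, the real one included, gave 11 or more lists, with a highest count of 16. The list calls below therefore rest on the preset correlation, and the gene counts beside them do not.

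All 26 measured members of the type I interferon response list rose, each by at least 1 on the log2 scale, with a median difference of 2.28, and 12 of them had a young mean within the negative control range. Camera gave an adjusted p = 2.27e-27, and adjusted p = 0.0885 with an estimated correlation. Adjusted over the list alone, 26 passed. Oas2, a sensor of double-stranded RNA, rose by 4.65 on the log2 scale, and Zbp1, a nucleic acid sensor, rose by 3.65. Irf7, a transcription factor that amplifies interferon production, rose from 7.65 ± 0.07 to 10.93 ± 0.01 (SD, n = 3 each), and Oas1a from 7.75 ± 0.07 to 10.70 ± 0.06.

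Of 15 measured antigen presentation genes 11 rose and 4 did not pass, 12 having passed when adjusted over the list alone. The median difference was 0.94 (camera, adjusted p = 1.71e-09, and adjusted p = 0.0734 with an estimated correlation). Tap1, which carries peptides into the endoplasmic reticulum, rose 4.25-fold, and the class I genes H2-K1, H2-D1 and H2-Q4 rose 3.17-fold, 2.64-fold and 3.90-fold. The class I genes are close paralogs, so their separate values are uncertain.

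In the unfolded protein response list 18 of 19 genes fell and none rose, with a median difference of -0.71, and 18 passed when adjusted over the list alone. Camera gave an adjusted p = 1.28e-14, and adjusted p = 0.0734 with an estimated correlation. Hyou1 went from 12.01 ± 0.00 to 10.64 ± 0.01 (SD, n = 3 each). Dnajc3 and Creld2 fell by 1.11 and 1.01 on the log2 scale, and Herpud1, a part of the degradation of misfolded proteins, fell by 0.81. Of 14 cytosolic ribosomal protein genes 11 fell and none rose, also when adjusted over the list alone. Their median difference was -0.16 (camera, adjusted p = 0.00113, and adjusted p = 0.151 with an estimated correlation). That median is close to the median difference of the positive control probe sets, -0.15, and smaller in size than that of the negative controls, -0.26. Rpl8 and Rps14 fell by 0.20 and 0.22. Rpl8 did not pass after quantile normalization.

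Of 29 extracellular matrix genes 21 rose, 3 fell and 5 did not pass, with 25 past the test when adjusted over the list alone. The median difference was 0.70 (camera, adjusted p = 2.04e-10, and adjusted p = 0.264 with an estimated correlation). The collagen VI genes Col6a1 and Col6a2 rose 4.30-fold and 4.68-fold, and Col3a1 and Col12a1 rose 3.61-fold and 3.32-fold. Among 19 matrix proteases and their inhibitors 15 rose and 1 fell, with 16 past the test when adjusted over the list alone and a median difference of 0.37 (camera, adjusted p = 1.85e-06, and adjusted p = 0.329 with an estimated correlation). Adamts1, a protease that cuts proteoglycans, rose 4.11-fold. Its list also holds protease inhibitors, of which Timp1 rose 1.87-fold, and Plat, the tissue plasminogen activator, rose 1.97-fold.

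Of 19 cholesterol and lipid synthesis genes 17 rose and none fell, with 18 past the test when adjusted over the list alone. The median difference was 0.72 (camera, adjusted p = 1.64e-09, and adjusted p = 0.329 with an estimated correlation). Idi1, an isomerase of the mevalonate pathway, rose from 6.53 ± 0.14 to 8.38 ± 0.06 (SD, n = 3 each), and Nsdhl, Elovl6 and Fdps rose 2.36-fold, 2.37-fold and 1.80-fold.

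Marrow stromal niche factors moved both ways: 9 of 17 rose and 4 fell, with 13 past the test when adjusted over the list alone. The median difference was 0.17 (camera, adjusted p = 0.0129, and adjusted p = 0.329 with an estimated correlation). Cxcl12, the chemokine that holds blood stem cells in the marrow, rose from 7.63 ± 0.01 to 9.87 ± 0.04 (SD, n = 3 each), a difference of 2.25. Its young mean lay at the edge of the negative control range, so no fold is given. Angpt1 and Gas6 rose by 3.45 and 2.79 on the log2 scale from 5.56 and 7.06, within the negative control range, and Kitl, the stem cell factor, rose by 0.20, less than the largest background shift, which is also upward. Nes (nestin) fell by 0.95. The leptin receptor gene Lepr was dim in both ages, at 4.18 ± 0.06 and 4.31 ± 0.07.

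Of 18 secreted inflammatory factors 10 rose and 2 fell, with 12 past the test when adjusted over the list alone and a median difference of 0.38 (camera, adjusted p = 0.00139, and adjusted p = 0.224 with an estimated correlation). Cxcl5, a chemokine for neutrophils, rose from 6.39, within the negative control range, to 9.52, Lcn2 rose 3.00-fold and Fgf7 rose 1.79-fold. Il6 went from 5.14 ± 0.15 to 6.13 ± 0.04 (SD, n = 3 each), both within that range, and Ptgs2 fell.

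**Figure D3:**
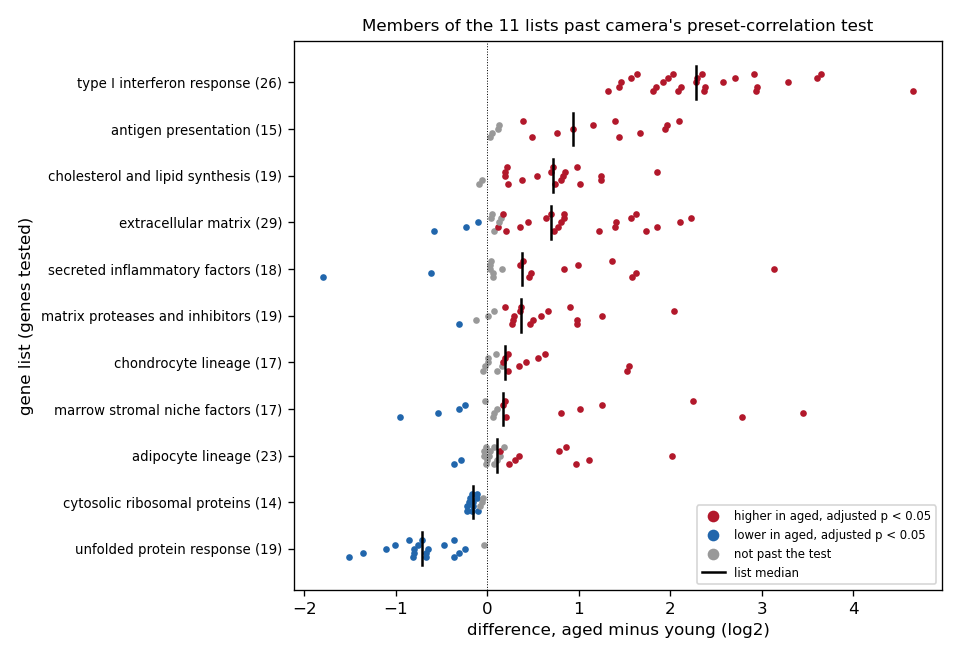
Difference of each measured member, aged minus young (log2, horizontal axis), for the 11 lists past camera with the preset correlation, with red and blue for members past limma's adjusted p threshold, grey for the rest and a black bar at each list's median. All 26 interferon genes lie to the right of 0, and the medians run from -0.71 to 2.28.

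Among lineage genes, 9 of 23 adipocyte genes rose and 2 fell, with 11 past the test when adjusted over the list alone and a median of 0.10 (camera, adjusted p = 0.0147, and adjusted p = 0.315 with an estimated correlation). Fabp4, a fatty acid carrier of fat cells, rose from 5.37 ± 0.08 to 7.39 ± 0.04 (SD, n = 3 each), both within the negative control range. Plin4 and Ebf1 rose 2.16-fold and 1.72-fold, and Fabp5 rose from 6.61 to 7.46, within that range. Pparg, the master regulator of fat cells, rose by 0.31. Cebpa and Lpl did not pass (limma, adjusted p = 0.112 and 0.374), and Adipoq was dim at 3.88 and 4.03. Of 17 chondrocyte genes 10 rose and none fell, also when adjusted over the list alone, with a median of 0.19 (camera, adjusted p = 0.00142, and adjusted p = 0.329 with an estimated correlation). Prg4 and Fmod, of joint and tendon matrix, rose from 6.60 and 5.85 to 8.12 and 7.39, and Sox9 rose 1.47-fold.

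Of 20 osteoblast genes 9 rose and 4 fell, with 13 past the test when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.0528). Alpl, the alkaline phosphatase of mineralisation, rose from 7.37 ± 0.05 to 8.66 ± 0.03 (SD, n = 3 each), Col1a1 rose 1.73-fold and Cdh11 rose 1.92-fold. Bglap, which encodes osteocalcin, fell by 0.43 and has a near-identical neighbour, so its value is uncertain. Sp7, a transcription factor of osteoblasts, was at 6.16 and 6.29 (limma, adjusted p = 0.0901).

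Of 14 senescence effectors 8 rose and 4 fell, with 12 past the test when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.0935). Cdkn2a, whose probe set cannot separate p16Ink4a from p19Arf, rose from 9.44 ± 0.05 to 10.20 ± 0.00 (SD, n = 3 each), or 1.69-fold. The cell cycle inhibitors Cdkn2b and Cdkn1a rose 2.90-fold and 2.01-fold. Gadd45a fell by 0.58, and Lmnb1 (lamin B1) fell by 0.15, a difference no larger than that of the positive controls, and one that did not pass after median centring. Of 29 proliferation genes 13 rose and 7 fell, with 21 past the test when adjusted over the list alone (camera, adjusted p = 0.274). Ccnb2 and Ccna2, cyclins of mitosis and S phase, rose 1.92-fold and 1.44-fold, and Mki67 rose by 0.22, less than the largest background shift, which is also upward. The 7 that fell, named after their values were seen, were Mcm2, Mcm3, Mcm4, Pcna, Rrm2 and Cdc6, which act in DNA replication, and the mitotic checkpoint gene Bub1, with differences from -0.40 to -0.24.

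The signalling lists moved both ways and none passed camera. Of 23 Wnt genes 9 rose and 5 fell (adjusted p = 0.116), with Sfrp1 and Rspo2 up by 1.95 and 1.68 on the log2 scale. Of 29 BMP and TGF-beta genes 12 rose and 8 fell (adjusted p = 0.116), with Fst up by 1.59. Of 18 Notch genes 7 rose and 1 fell (adjusted p = 0.216), with Jag1 up 1.78-fold. Of 22 hedgehog, FGF and IGF genes 9 rose and 5 fell (adjusted p = 0.0935), with Spry1 up 2.41-fold. Adjusted over the list alone, 14, 22, 9 and 14 of these genes passed. The genes named all rose, and the lowest differences in these lists, in the same order, were -0.74, -0.59, -0.30 and -0.45 on the log2 scale.

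Of 22 antioxidant genes 8 rose and 10 fell (camera, adjusted p = 0.454), among them Hmox1, which fell by 1.08, Txnrd1, which fell from 11.85 to 10.85, and Gpx3, which rose from 7.02 to 9.10. Of 23 glycolysis and hypoxia genes 5 rose and 12 fell (adjusted p = 0.0935). Adm rose from 6.30 to 7.71, and the lowest difference in that list was -0.73 on the log2 scale. Of 21 DNA repair genes 1 rose and 10 fell (adjusted p = 0.0817). Of 20 autophagy and lysosome genes 2 rose and 7 fell (adjusted p = 0.283), of 27 respiratory chain genes 4 rose and 4 fell (adjusted p = 0.804), and of 23 immediate early and heat shock genes 9 rose and 6 fell (adjusted p = 0.443). Adjusted over the list alone, 21, 19, 11, 9, 5 and 15 of these genes passed.

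No list of markers of other marrow and bone cells passed camera, though single markers rose beside the matrix and niche genes. Myl9, of smooth muscle, rose 2.35-fold, Ctsk, a protease of osteoclasts, rose 1.97-fold, and the endothelial marker Kdr rose from 5.93 to 6.62, within the negative control range. Of the sort markers, Ly6a (Sca-1) had no single-gene probe set here and was not analysed. Itgb1 (CD29) was bright at 11.86 and 11.76, and its small decrease did not pass after quantile normalization. Ptprc (CD45) was at 3.65 and 3.62 and Itgam (CD11b) at 5.26 and 5.24, within the negative control range. Of 13 macrophage and monocyte markers 2 rose (camera, adjusted p = 0.434), of 10 neutrophil markers 3 rose (adjusted p = 0.13), of 10 B cell markers 1 rose (adjusted p = 0.144), and of 10 T and NK cell markers 3 rose (adjusted p = 0.248). The B cell marker that rose was Ebf1, which stromal cells also express. Of 9 osteoclast markers 2 rose (adjusted p = 0.136), of 9 erythroid markers 1 rose (adjusted p = 0.345), and of 9 megakaryocyte and mast cell markers 1 rose and 1 fell (adjusted p = 0.305). Ppbp, a platelet chemokine, was the megakaryocyte marker that rose, from 6.53 to 8.95. Of 16 endothelial markers 3 rose and 2 fell (adjusted p = 0.216), of 13 pericyte and smooth muscle markers 7 rose and 2 fell with a median difference of 0.20 (adjusted p = 0.0729), of 13 skeletal muscle markers 1 rose (adjusted p = 0.283), and of 10 Schwann and neural markers 2 rose (adjusted p = 0.216). Adjusted over the list alone, 2, 1, 1, 3, 2, 1, 1, 2, 11, 0 and 2 of these markers passed, in the order given.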

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

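All tests in this part were chosen after the results were seen. Control probe sets, which the comparison of genes does not use, differed between the ages. Of 5222 negative control probe sets 317 passed (limma, Benjamini-Hochberg adjusted p under 0.05), with a median difference of -0.26. Array medians were 5.06, 5.01 and 4.93 in young arrays 1 to 3 and 4.62 to 4.67 in aged arrays. Of 1324 positive control probe sets 539 passed, with a median difference of -0.15. Their array medians were 9.91, 9.85 and 9.80 in young arrays 1 to 3 and 9.75 to 9.77 in aged arrays. Both kinds thus fell across the young arrays toward the aged values. The antigenomic background classes went the other way: all 23 were higher in aged arrays, the 4 richest in G and C (22 to 25 bases) passed, and the largest difference was 0.29. Of 155 ERCC spike-in probe sets 0 passed with limma, and 10 had an unadjusted p under 0.05. Their median level was 5.21 in young and 5.33 in aged arrays, within the negative control range, so they say little on whether the arrays differ. The median differences of the control kinds kept their sign under quantile normalization and median centring, which could change them little because the array medians were already close.

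A lower background or scaling of the aged arrays as the source of the lower negative controls is argued against by the antigenomic probes, whose median difference was 0.11 with a lower quartile of 0.07. Less unspliced or nuclear RNA in the aged samples may be another source. Of 358 small nucleolar RNA genes 108 fell and 6 rose, with a median difference of -0.11, but the positive controls were lower too, so these values do not decide it. Age itself stays open and untested here.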

How the results depend on the processing

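The test against a difference of 0.3 was chosen after the data were seen. Genes differing with age numbered 8195 and 6715 to 9301 with each array left out in turn, and 7478 to 7715 of them were also called under median centring and quantile normalization. Median centring gave 50.7% of calls higher, against 45.4%. With every probe set past the filter tested in place of genes, 10852 of 32978 were called. Against a difference of 0.3 the count was 1985, since that test asks for larger differences. Genes at least 2-fold different numbered 449 to 462 with each array left out. Shifted lists numbered 17 with no filter on dim probe sets, where the cause was not tested, and 0 with an estimated correlation. Camera with an estimated correlation ended all 11 list calls. It takes the correlation from only 6 arrays, so it cannot tell whether correlation between genes accounts for the shifts. The 26 genes of the interferon list all rose by at least 1.32 on the log2 scale. Even so, camera with that estimate gave this list an unadjusted p of 0.00759. The adjusted p were unfolded protein response 0.0734, antigen presentation 0.0734, interferon response 0.0885, ribosomal proteins 0.151 and inflammatory factors 0.224. They were extracellular matrix 0.264, adipocyte 0.315, and 0.329 each for cholesterol synthesis, matrix proteases, chondrocyte and niche factors. At the preset correlation the adjusted p of these 11 lists stayed at or below 0.0231 in the other refits run for lists (scaling, filter, probe set rule, eBayes options, block and arrays left out). With the replicate block 7728 genes, 453 genes of at least 2-fold and 11 lists were called. Deviations of same-numbered arrays from the mean of their age correlated at -0.05, 0.07 and 0.02, so no pairing by number was seen. With so few arrays per age, a preparation shared by same-numbered arrays cannot be excluded. Of 2080 comparisons of 150 named genes with an alternative, 51 lost the call, 1 gained it and 0 reversed; of 355 for the 24 lists not called, 13 gained it. A pseudocount did not apply, as the values are already log2. Signal over background limits genes near the filter, and the 10 splits of the arrays are too few for a share under 0.05: the real split gave 8195 genes, 453 of at least 2-fold and 11 lists, and the highest of the others gave 0, 0 and 16, with 1 split for each gene count and 4 for the lists as high as the real one. Each other split mixes the ages and keeps part of the age difference, so its counts do not measure chance. For these splits limma gave 119 to 566 genes at an unadjusted p under 0.05.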

Other observations

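The tests of this part were chosen after the results were seen, and so were the genes named here outside the lists. Grouping genes by the start of their symbol gave 508 families of at least 5 tested genes, of which 49 passed camera at the preset correlation and 0 with an estimated correlation. All 7 guanylate-binding protein genes (Gbp), interferon-inducible GTPases, rose, with a median difference of 2.36 (camera, adjusted p = 4.82e-08, and adjusted p = 0.943 with an estimated correlation). Gbp3 went from 7.78 ± 0.14 to 10.86 ± 0.02 (SD, n = 3 each) and Gbp2 from 8.54 ± 0.11 to 11.19 ± 0.01. All 5 Schlafen genes (Slfn) rose, with a median of 1.39 (adjusted p = 0.000139, and adjusted p = 0.943 with an estimated correlation). Of 13 genes of the clade B serine protease inhibitors (Serpinb) 12 rose and 1 fell, with a median of 0.65 (adjusted p = 1.89e-05, and adjusted p = 0.943 with an estimated correlation). Of the 13 Serpinb genes, 10 had a young mean within the range of 95% of the negative controls and 8 had both means there. That median therefore mostly compares values within that range, where the true ratio is not known. Of the Gbp and Slfn genes, 3 and 2 had a young mean in that range. Members of these families are close paralogs and single values are uncertain.

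Of 17 nucleoporin genes (Nup), which build the nuclear pore, 13 fell and 1 rose, with a median difference of -0.31 (camera, adjusted p = 0.000139, and adjusted p = 0.943 with an estimated correlation). Nup88 and Nup205 fell by 0.54 and 0.51 on the log2 scale, and Nup37 rose by 0.22, less than the largest antigenomic background shift of 0.29. Of 17 lysine demethylase genes (Kdm) 11 fell and none rose, with a median of -0.25 (adjusted p = 0.00189, and adjusted p = 0.943 with an estimated correlation). Kdm7a and Kdm3a each fell by 0.79. Of 39 Snord and 18 Snora genes, small nucleolar RNAs that guide changes of ribosomal RNA, 24 and 13 fell and none rose (adjusted p = 0.000323 and 0.00217, and adjusted p = 0.943 for both with an estimated correlation). The Kdm, Snord and Snora medians (-0.25, -0.21 and -0.22) are no larger in size than the median shift of the negative control probe sets, -0.26, and 3, 5 and 7 of their genes had both means within the negative control range. The families named here kept the sign of their median under quantile normalization and median centring. Those refits could change the medians little, because the array medians were already close, so they add nothing on this point.

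The interferon list had a median array level of 7.62 to 7.74 in young and 10.13 to 10.16 in aged arrays. A shift of whole arrays in the deposited values is argued against as the source, since the median difference of all tested genes was 0.01. The list's median difference was at least 2.27 under quantile normalization and median centring. Those refits could change it little, because the array medians were already close, so they add nothing on this point. Immune cells carried through the sort are argued against by their markers as sets, and the sort excluded CD45 and CD11b. The 68 macrophage, neutrophil, B cell and T cell markers, dim ones included, had a median difference of 0.0665 and an upper quartile of 0.12. A single lineage could be hidden in that pooled median. Taken singly, the tested members of these lists had medians of 0.06, 0.13, 0.09 and 0.06, and 2, 3, 1 and 3 of them rose. An exposure shared by the cultures of the aged mice may also raise the list; the lowest aged array lay 2.39 above the highest young one, which that and an effect of age both predict, and the design does not separate them.

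Neither Xist nor the Y-linked genes Kdm5d, Eif2s3y and Uty gave a signal in any array of either age. The highest array value of Xist lay above 39.8% of the negative control probe sets, and that of the Y-linked genes above 41.1%. Their X-linked relatives Kdm5c and Eif2s3x were at 9.38 and 11.14 in young cells. Probe sets that do not respond, or cells that express neither, may each account for this, and no value here decides between them; the sex of the mice is not given in the sources used here.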
